A study of Streptomyces coelicolor with 6 samples.

How the data were processed

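RNA was sequenced from Streptomyces coelicolor A3(2) M145 in 3 groups of 2 libraries each: wild type, wild type exposed to 25 µM H2O2 for 10 min, and a catR mutant. Cultures grew in YEME with 5 mM MgCl2 and 10% sucrose to an OD600 of 0.4. Per the protocol, RNA was extracted with a modified Kirby mix and treated with DNase I, ribosomal RNA was depleted with Ribo-Zero, and stranded TruSeq libraries were sequenced on an Illumina HiSeq. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 2.2.5, featureCounts, Subread 1.5.3 and DESeq2. The genome build, annotation, strand setting, DESeq2 version and model formula were not given in the sources used here.

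The deposited tables, one per comparison, hold results of the authors' DESeq2 fit for 7854 locus tags, of which 2 are listed at 0. The signal columns of the authors' tables are the mean of normalised counts over the libraries of their fit and, in the mutant table, the mean of normalised counts over the wild-type libraries. The log2 columns deposited by the authors are the fold change over wild type and its standard error. The score column deposited by the authors is the Wald statistic, the fold change divided by that error. The p-value columns deposited by the authors are a two-sided p-value and its Benjamini-Hochberg adjustment. The files pair no gene names or products with locus tags, and 0 of the 7854 tags were found in the reference table. Names in the text come from lists written before the data were examined and from textbook knowledge.

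The tables were checked in several ways. The adjusted p was recomputed to within 0.001, and was missing for 759 genes of the H2O2 table with a mean of up to 13.5. The direction of each fold change was checked by rebuilding the deposited mean from the group means over 5715 genes. The spread of the log2 ratio was 0.180 with both signs as read and at least 0.405 otherwise. The wild-type mean was resolved into whole reads of its 2 libraries for 7598 genes (96.7%), with size factors of 1.37 and 0.623. Values shifted at random gave such a solution by chance in 0.132% of genes. Over 5291 genes with a wild-type mean of at least 50, the wild-type libraries had an SD of the log2 ratio of 0.59, and 357 genes were over 2-fold apart. Over genes with a mean of at least 50, the median standard error of the log2 fold change was 0.36 in both comparisons. The median log2 fold change over all genes was 0.02 in the mutant and 0.00 after H2O2. No per-library value was available for the other groups.

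Gene calls were the authors' log2 fold change and adjusted p below 0.05, as deposited. Group counts were also adjusted over the list alone. The 27 gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' statistic, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The lists covered the neighbourhood of SCO2027, Fur-family regulators, catalases, OxyR and AhpC, superoxide dismutases, thiol stress, SoxR, zinc uptake, coelibactin, desferrioxamine, coelichelin, bacterioferritin and Dps, Suf, chaperones, DNA damage, SigB, ectoine, sulfate assimilation, actinorhodin, undecylprodigiosin, calcium-dependent antibiotic, coelimycin, S10-spc ribosomal proteins, ATP synthase, nuo, aerial surface proteins and gas vesicles. A correlation could not be estimated without per-library values. Lists defined on product text could not be applied. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

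The groups, tests, lists, thresholds and the rule for named genes were chosen before the data were examined. The rule took the regulator, catalase, OxyR and AhpC, superoxide dismutase and SCO2027 lists whatever their values. It added per comparison the 10 largest increases and decreases among called genes with a mean of at least 50 other than rRNA and tRNA, and up to 4 members of every other list. Alternatives chosen with them were a mean of at least 50, an absolute log2 fold change of at least 1, an adjusted p below 0.01, removal of rRNA- and tRNA-numbered tags, adjustment over all genes with a p, a preset correlation of 0.05, ranks, and the log2 fold change as statistic. Alternatives added after the data were examined were the removal of a trend of the log2 fold change on the mean (lowess, span 0.3), a limit of 2-fold between the wild-type libraries, a different wild-type library under each comparison for the correlation across genes, and a test of the difference between both fold changes. That test uses the root of the summed squared standard errors, which is too large because both share the wild type.

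The steps were tested on simulated data. Resolved read counts were right for 100% of genes. Noise was drawn from the deposited standard errors, so those errors were not themselves tested. With the abundance trend of the mutant table kept, the test found 90.4% of genes changed by 2 on the log2 scale. It also called 111 unchanged genes, meaning genes given no change beyond that trend. These are false calls only if the trend is technical, which stays open. With the trend removed it found 90.7% and called 7.70 unchanged genes. For the H2O2 table the unchanged genes called were 10.6 and 6.60. The difference test found 95.9% of genes differing by 3. The list test found 100% of lists in which every member's statistic was shifted by 3, and called 0.2 unshifted lists per run. Members were simulated as independent, so this does not show how the test behaves on lists of correlated genes.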

Results

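Transcript levels were measured by RNA sequencing in Streptomyces coelicolor A3(2) strain M145, a soil bacterium with a complex life cycle. Cultures in liquid YEME medium were sampled at an OD600 of 0.4. There were 3 groups of 2 libraries each: untreated wild type, wild type exposed to 25 µM H2O2 for 10 min, and an untreated catR mutant. CatR is a peroxide-sensing repressor of the Fur family. The series design calls the duplicates biologically independent. The files gave the results of the authors' test for 7854 locus tags, not values per library, so each fold change carries the authors' standard error. Which libraries entered the authors' fit is not given in the sources used here. If any beyond these 6 did, the standard errors, adjusted p and overall mean rest on those as well. So do the abundance trend and the limit of a mean of at least 50 used below. For 3 genes described below, the overall mean argues against these 6 alone. The wild-type mean could be split into whole reads of its 2 libraries for 7598 genes, with size factors of 1.37 for the deeper and 0.623 for the shallower library. The 256 genes not split were all above a mean of 8943 normalised counts and held 66.3% of the normalised wild-type total. The total depth of the libraries is unknown.

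The first comparison asked which transcripts differ between the catR mutant and the wild type. The transcript of catR itself (SCO5206) was 4.31-fold lower in the mutant, with a log2 fold change of -2.11 ± 0.36 (standard error) in the authors' deposited table. That left a mean of 186 normalised counts. The mutant libraries are titled dcatR, and the mutation is not otherwise described in the sources used here. SCO0379, the catalase gene catA, was 61.6-fold higher, with a log2 fold change of 5.94 ± 0.34 and the authors' adjusted p = 7.5e-64 in the authors' deposited table. SCO2027, the gene in the title of the series, was 61.9-fold higher, at 5.95 ± 0.50 with an adjusted p = 1.3e-29 in the authors' deposited table. Of the genes for siderophores, the secreted iron chelators, 5 of 5 for desferrioxamine and 8 of 11 for coelichelin fell. In all, 270 genes had an authors' adjusted p below 0.05, a threshold set here. Of these, 123 were higher and 147 lower in the mutant in the authors' deposited table.

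The rise of catA extended over 23 consecutively numbered locus tags, SCO0379 to SCO0401, all of them past the test. Their log2 fold changes lay between 2.13 and 6.17 in the authors' deposited table. Of the other catalase genes, catC (SCO0560) was at -0.08 ± 0.31, catB (SCO0666) at 1.05 ± 0.40 and SCO7590 at 0.58 ± 0.37, none past the threshold in the authors' deposited table. The catalase list passed upwards (limma's cameraPR, adjusted p = 2.0e-10), with catA as the 1 of its 4 members called over all genes and 2 called adjusted over the list alone. By ranks the catalase list missed the threshold, with an adjusted p of 0.057. Of the 5 tags of the SCO2027 list, SCO2025 to SCO2029, 2 rose over all genes tested, SCO2027 itself among them, and 3 adjusted over the list alone. The other called tag, SCO2028, had a log2 fold change of 3.71 ± 0.83 from a wild-type mean of 3.79 normalised counts in the authors' deposited table. SCO2025 and SCO2026 were at 0.96 ± 0.50 and 0.48 ± 0.68 and missed the threshold in the authors' deposited table. The neighbourhood list, with SCO2027 in it, had an adjusted p of 1.1e-08 in cameraPR, which does not separate the neighbours from SCO2027.

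Alkyl hydroperoxide reductase, which removes peroxides, was lower in the mutant. The transcripts of ahpD (SCO5031) and ahpC (SCO5032) fell by 3.53 ± 0.47 and 2.90 ± 0.48 on the log2 scale in the authors' deposited table. The gene of their regulator OxyR (SCO5033) was at -0.40 ± 0.45 and not past the threshold in the authors' deposited table. The OxyR and AhpC list gave an adjusted p of 5.5e-07 in cameraPR, with 2 of 3 members called, both over all genes and adjusted over the list alone. The other Fur-family genes furA (SCO0561), nur (SCO4180) and zur (SCO2508) lay between -0.43 and -0.16 without a call in the authors' deposited table. Of the Fur-family list, catR, the gene mutated in this strain, was the 1 member of 4 called, over all genes and adjusted over the list alone. The list, with that gene in it, had an adjusted p of 0.0075 in cameraPR, and missed the threshold with the log2 fold change as statistic (0.077) and with the abundance trend described below removed (0.089). Superoxide dismutase genes had no call over all genes. Adjusted over the list alone 1 of 3 was called, namely sodF (SCO2633), with a log2 fold change of 1.18 ± 0.42 in the authors' deposited table. The median of that list was -0.09 while its test pointed upwards (adjusted p = 0.56, and 0.014 with the abundance trend removed).

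All 5 desferrioxamine genes fell, by 2.58 to 3.95 on the log2 scale in the authors' deposited table. The strongest was desA (SCO2782), which was 15.5-fold lower. Of the 11 coelichelin genes, 8 fell over all genes tested and 11 adjusted over the list alone. Both lists passed cameraPR, with adjusted p of 2.3e-14 and 1.5e-17, and of 1.6e-12 and 6.5e-13 with a preset correlation of 0.05. The largest decrease of any called gene was that of SCO2271, at -4.03 ± 0.45 in the authors' deposited table, within a run of 8 lower tags from SCO2267 to SCO2274. SCO1488 was at -3.92 ± 1.21 with an adjusted p of 0.040 in the authors' deposited table. With the abundance trend removed its log2 fold change was -3.46 and its adjusted p 0.16, at the same wide standard error.

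Fold changes in the mutant depended on abundance. The median log2 fold change was 1.31 over the 557 genes with a mean of at most 10 normalised counts and -0.56 over the 210 genes above 10000. With a smooth trend on abundance removed, a step added after the data were examined, 129 genes passed, 70 higher and 59 lower, and 119 of the 270 kept their call and direction. Several list results moved with it. The S10-spc ribosomal protein list and the ATP synthase list, both with a median log2 fold change of -0.69, went from adjusted p of 2.9e-07 and 0.0011 to 0.49 and 0.60 in cameraPR. Most genes of both lists had a mean above 10000 and so helped set the trend. Its removal therefore cannot show that they were unchanged. The actinorhodin, undecylprodigiosin and coelimycin clusters, with medians of 0.37, 0.81 and 0.59, went from adjusted p of 0.031, 0.0012 and 0.012 to 0.64, 0.24 and 0.26. None of the genes in these lists was called over all genes tested, against 3 coelimycin genes higher and 3 ATP synthase genes lower adjusted over the list alone. With a preset correlation of 0.05 the actinorhodin and coelimycin lists were at adjusted p of 0.13 and 0.068. The calcium-dependent antibiotic cluster had an adjusted p of 6.4e-07, and of 0.0040 with the trend removed, with 2 of 40 members higher over all genes and 6 higher and 1 lower adjusted over the list alone. With a mean of at least 50 that list was at an adjusted p of 0.089.

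**Figure D1:**
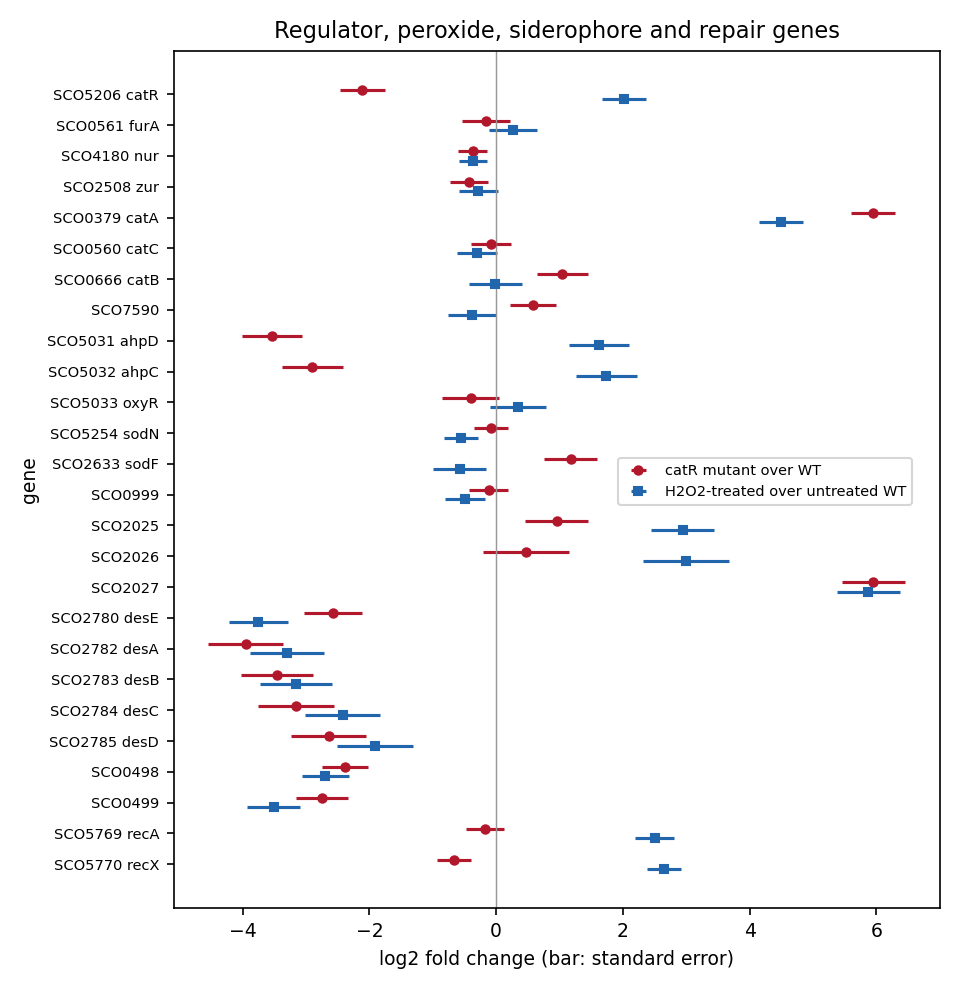
log2 fold changes in the authors' deposited table (horizontal axis, log2 units) of single genes (vertical axis), with bars for the standard error; circles stand for the catR mutant over wild type and squares for H2O2-treated over untreated wild type. SCO2027 lies at 5.95 and 5.87, while catR lies at -2.11 and 2.02.

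The second comparison asked which transcripts respond to H2O2 in the wild type within 10 min. SCO2027 rose 58.4-fold, at 5.87 ± 0.50 with the authors' adjusted p = 6.8e-29 in the authors' deposited table. The catalase gene catA rose 22.5-fold, at 4.49 ± 0.34 with an adjusted p = 4.4e-36 in the authors' deposited table. The transcript of catR rose 4.04-fold, at 2.02 ± 0.35 in the authors' deposited table. The DNA repair gene recA rose, while 5 of 5 desferrioxamine and 7 of 11 coelichelin genes fell. In all, 299 genes passed, of which 200 were higher and 99 lower after H2O2 in the authors' deposited table.

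After H2O2 the run of higher tags that starts at catA ended at SCO0386 and held 8 tags, with log2 fold changes between 1.98 and 6.81 in the authors' deposited table. The largest increase was that of SCO0381, at 6.81 ± 0.50 from a wild-type mean of 13.7 normalised counts in the authors' deposited table. The other catalase genes catB, catC and SCO7590 were at -0.01 ± 0.42, -0.30 ± 0.31 and -0.38 ± 0.38 without a call in the authors' deposited table. The catalase list had an adjusted p of 0.0019 upwards in cameraPR although its median was -0.16, since catA alone was called, over all genes and adjusted over the list alone. By ranks the list pointed the other way, with an adjusted p of 0.92. Of the 5 tags of the SCO2027 list, 3 rose over all genes, SCO2027 itself among them, and 4 adjusted over the list alone. That list, with SCO2027 in it, had an adjusted p of 3.1e-12 in cameraPR. SCO2025 rose by 2.95 ± 0.50 on the log2 scale with an adjusted p of 2.6e-07, and SCO2026 passed at 0.00044, in the authors' deposited table. The increase of SCO2025 was 7.70-fold, and neither gene passed a test of the difference from the mutant (adjusted p of 0.17 and 0.25). The 2 wild-type libraries were at 2067 and 8963 normalised counts for SCO2026.

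Alkyl hydroperoxide reductase rose after H2O2, with ahpD at 1.62 ± 0.47 and ahpC at 1.74 ± 0.48 in the authors' deposited table. Both passed at 0.05 and missed a threshold of 0.01. The OxyR and AhpC list had 2 of 3 members called over all genes and adjusted over the list alone, and an adjusted p of 0.016 in cameraPR. Of the DNA damage list, the recombinase gene recA (SCO5769) rose 5.65-fold and its regulator gene recX (SCO5770) 6.27-fold. The latter was at 2.65 ± 0.27 with an adjusted p of 3.5e-20 in the authors' deposited table. These were 2 of 6 members called over all genes, against 3 adjusted over the list alone, with an adjusted p of 1.4e-09 in cameraPR. The excision repair gene uvrA (SCO1958), at 1.52 ± 0.41 in the authors' deposited table, was the 1 of 19 thiol stress genes called, both over all genes and adjusted over the list alone. That list did not pass (adjusted p = 0.42), with a median of -0.01 while its test pointed upwards. The nuo genes of NADH dehydrogenase had 3 of 14 members higher over all genes and 8 adjusted over the list alone, with an adjusted p of 3.0e-05 in cameraPR. Among them SCO4570 was at 1.56 ± 0.42 from a wild-type mean of 38.6 normalised counts in the authors' deposited table.

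After H2O2 the 5 desferrioxamine genes were all lower, between -3.75 and -1.91 in the authors' deposited table, and 7 of 11 coelichelin genes were lower over all genes and 10 adjusted over the list alone. Their lists had adjusted p of 1.7e-13 and 7.0e-25 in cameraPR, and of 9.5e-12 and 2.5e-18 with a preset correlation of 0.05. The actual correlation among these neighbouring genes could not be estimated. The largest decrease was that of SCO0194, at -4.78 ± 0.50 in the authors' deposited table, within a run of 5 lower tags from SCO0192 to SCO0196. The 8 sulfate assimilation genes had a median of 1.76 with standard errors above 1 and no call, over all genes or adjusted over the list alone. Their list had an adjusted p of 0.093, and passed upwards by ranks (0.0027) and by log2 fold change (3.6e-10). For SCO6102, a member of that list, the 2 wild-type libraries were at 413 and 3550 normalised counts. The S10-spc ribosomal and ATP synthase lists, with no member called, were both at an adjusted p of 0.042 in cameraPR. They went to 0.17 and 0.095 with a preset correlation of 0.05, and to 0.83 and 0.39 with the abundance trend removed.

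**Figure D2:**
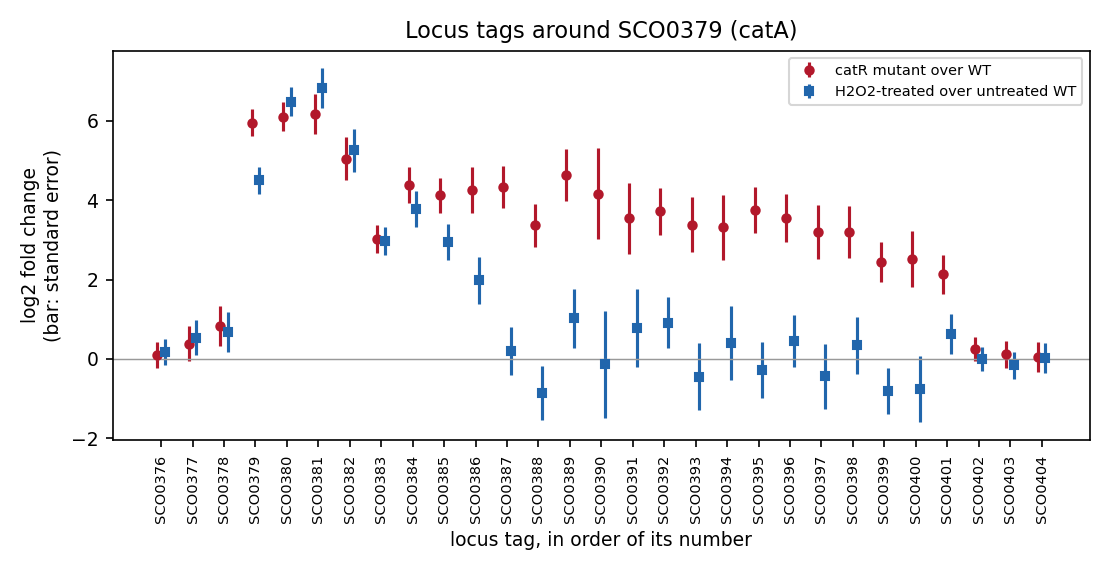
log2 fold changes with standard errors in the authors' deposited table (vertical axis, log2 units) for locus tags around catA in the order of their numbers (horizontal axis); circles stand for the catR mutant over wild type and squares for H2O2-treated over untreated wild type. The run of higher tags holds 23 tags in the mutant and 8 after H2O2.

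Zinc uptake, coelibactin, bacterioferritin and Dps, chaperones, the SigB group, ectoine, SoxR targets, aerial surface proteins and gas vesicles had no member called, over all genes or adjusted over the list alone, and did not pass cameraPR in the mutant or after H2O2. Their adjusted p lay between 0.12 and 0.92 in the mutant and between 0.32 and 0.91 after H2O2. Other statistics put 3 of them past the test: in the mutant gas vesicles passed upwards by ranks (0.034) and aerial surface proteins upwards by log2 fold change (0.036), and after H2O2 coelibactin passed downwards by log2 fold change (0.014). The SigB group had a median of 0.28 in the mutant while its test pointed downwards. The Suf iron-sulfur genes had no call either, with adjusted p of 0.88 and 0.42 and, with the abundance trend removed, 0.049 upwards in the mutant. The DNA damage list had no call in the mutant (adjusted p = 0.37), where recA was at -0.18 ± 0.30 in the authors' deposited table. The thiol stress, nuo and sulfate lists had no call over all genes in the mutant either, against 1 nuo gene adjusted over the list alone, with adjusted p of 0.099, 0.078 and 0.82. By ranks the thiol stress list passed downwards and the nuo list upwards in the mutant, at 0.030 and 0.040. After H2O2 the superoxide dismutase, actinorhodin, undecylprodigiosin, calcium-dependent antibiotic and coelimycin lists had no call, with adjusted p of 0.13, 0.46, 0.38, 0.86 and 0.42. The superoxide dismutase list passed downwards by ranks (0.038), and the calcium-dependent antibiotic list had a median just above 0 while its test pointed downwards. The Fur-family list, with catR as its 1 call after H2O2 over all genes and adjusted over the list alone, was at 0.38, with a median of -0.01 while its test pointed upwards.

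The last question was how far the genes called in the catR mutant and the H2O2 response overlap. In both comparisons 15 genes were higher and 47 lower, where independent lists of the same sizes among the 7093 genes tested in both would share 3.10 and 2.05. The 15 were SCO0379 to SCO0386, SCO2027, SCO4980 to SCO4983, SCO4882 and SCO5447, where tags outside the rule for named genes were chosen after their values were seen. The 47 held all 5 desferrioxamine genes, 6 coelichelin genes and the runs SCO2267 to SCO2274, SCO4047 to SCO4052 and SCO7397 to SCO7400. Another 4 genes went opposite ways, higher after H2O2 and lower in the mutant: catR, ahpC, ahpD and SCO1342, the last of which was also chosen after its values were seen. Both comparisons share the same wild-type libraries, so part of the excess may come from these. Simulated unchanged groups, with 50% and 90% of the error variance placed in the wild type, gave 0 and 0.01 genes called in both, which leaves out real effects and the abundance trend and so does not measure what shared error adds to real calls. The covariance of the log2 fold changes over 5715 genes was 0.162, against 0.0838 and 0.151 in these simulations. Pearson's r across genes, which are not independent replicates, was 0.389, against 0.496 and 0.893, and Spearman's rho was 0.291. Each comparison was then set against a different wild-type library, a step added after the data were examined, over the 5459 genes with both libraries resolved. The covariance there was 0.161 with the shared mean. It was 0.127 with the mutant over the deeper and H2O2 over the shallower library, and 0.0228 the other way round, with r of 0.283 and 0.0413 and rho of 0.121 and -0.0857. The correlation over all genes thus depended on the wild-type library used. Of the genes called in both with both libraries resolved, 15 of 15 higher and 46 of 46 lower genes had the same direction over each library, though they were picked by these calls. A test of the difference, added after the data were examined, which ignores the shared wild type and so is too strict, found 143 genes, 35 with the mutant effect above the H2O2 effect and 108 with it below.

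**Figure D3:**
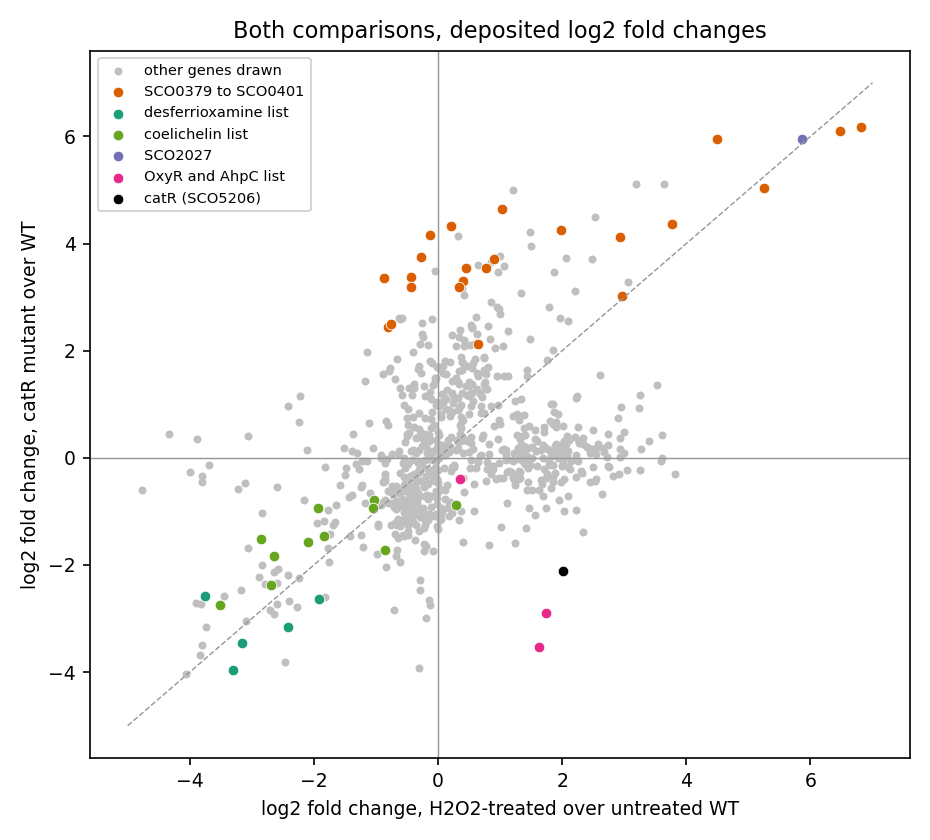
log2 fold changes in the authors' deposited table after H2O2 (horizontal axis, log2 units) and in the catR mutant (vertical axis, log2 units). Points are genes called in either comparison or held in a list. Some further tags without a call are drawn too, among them tags around catA and SCO3982 to SCO3988. The dashed line marks equal values. SCO2027 and SCO0379 to SCO0386 stand at the upper right, the 5 desferrioxamine and 10 of 11 coelichelin genes at the lower left, and catR, ahpC and ahpD at the lower right.

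**Figure D4:**
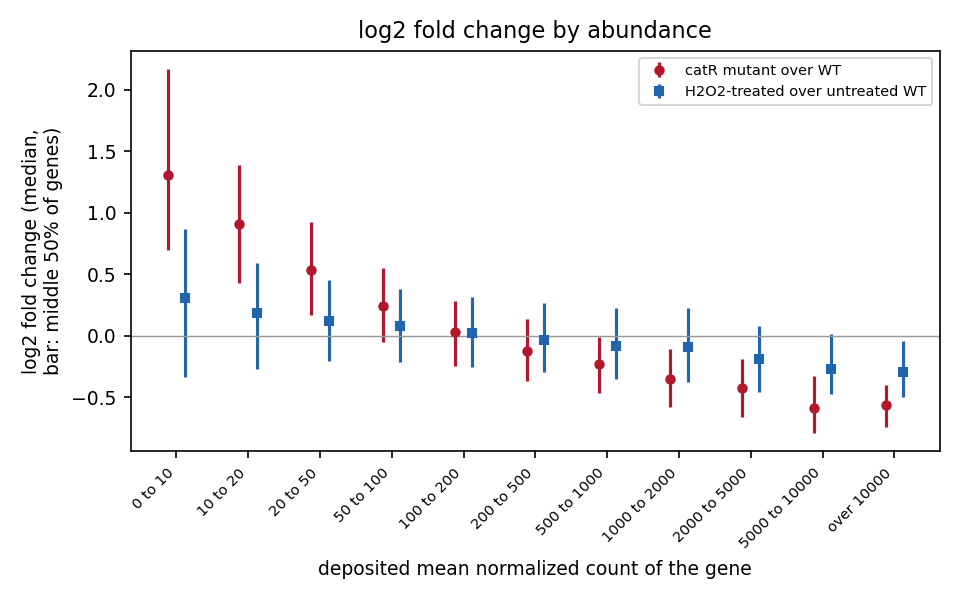
Median log2 fold change (vertical axis, log2 units; bars span the middle 50% of genes) by the deposited mean normalised count (horizontal axis, ranges of counts). The median falls from 1.31 to -0.56 in the catR mutant (circles) and from 0.31 to -0.30 after H2O2 (squares).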

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

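The tests of the difference between both comparisons, of the deposited mean and of the run after SCO0379 were chosen only after the result was seen.

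In 4 genes the transcript was called lower in the mutant and higher after H2O2. They were picked by these opposite calls, so that they also passed the test of the difference adds little. For catR (SCO5206), the gene mutated in the strain with the lower value, the difference, mutant minus H2O2, was -4.12 with a standard error of at most 0.50, and for ahpD (SCO5031) and ahpC (SCO5032) it was -5.16 and -4.64. SCO1342, chosen after its values were seen, had a difference of -3.72 (adjusted p = 1.2e-15, from the standard errors of the authors' DESeq2 fit).

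In 3 genes, also chosen after their values were seen, the deposited mean lay over 2 times above the level of every group, among 5079 genes with a mean of at least 50 and wild-type libraries within 2-fold of each other. The ratio to the highest group mean was 5.13 for SCO2985, 9.55 for SCO2986 and 3.07 for SCO5034. Without the limit on the wild-type libraries 12 genes had a ratio over 2, and the other 9 had ratios of 2.07 to 3.52. Their standard errors were 0.66 to 1.93, against at most 0.40 in the first 3, so libraries that disagree within a group cannot be told apart from other sources for the 12 genes as a set. For the first 3 genes, ratios of 3.07 to 9.55 at these errors argue against a mean over the 6 libraries alone. Libraries beyond the 6 are a candidate source and were not analysed here. The design text mentions treated mutant libraries, which were not tested as that source. The rule looked only for means above every group. For SCO0379 the deposited mean of 44231 lay below the average of the 3 group means. Those follow from a wild-type mean of 2275 and log2 fold changes of 5.94 and 4.49. To lower it, added libraries would have to lie below that average, and the level in treated mutant libraries is not known here. No biological explanation was tested.

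The run of higher tags that starts at catA went on from SCO0387 to SCO0401 in the mutant, while none of the 12 of these 15 tags with an adjusted p after H2O2 was called higher, and 8 of the 15 passed the difference test. Reads spilling over from SCO0379 would give these tags its share of increase after H2O2, 0.355 (95% interval 0.182 to 0.706). The tags' share of 0.0133 (-0.00936 to 0.0744) argues against that, as does 0.0142 (-0.00995 to 0.0785) without SCO0387, the tag picked because the H2O2 run ended there. The abundance trend is argued against as the whole source, since 11 of the 15 tags were still higher with it removed. A longer response in a strain with a lasting mutation of the repressor gene than after 10 min of treatment may be a candidate explanation and was not tested, and other differences of the mutant strain stay open.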

How the results depend on the processing

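The trend removal, the uses of single wild-type libraries and the difference test were chosen only after the results were seen. The count of 270 genes in the mutant went to 135 at an adjusted p below 0.01 (57 higher, 78 lower), by construction of a stricter threshold, and to 129 with the abundance trend removed (70 higher, 59 lower). The 123 higher genes went to 72 with a mean of at least 50, where fewer genes were tested. The other alternatives gave 229 to 270. After H2O2 the count lay between 227 and 307 under every alternative run, and the overlap between 52 and 65. The covariance of both fold changes, 0.162, went to 0.127 and 0.0228 with a different wild-type library under each comparison, where no library is shared. The difference test gave 125 genes with the trend removed. Lists past the test numbered 8 to 14 in the mutant and 7 to 10 after H2O2. The Suf list turned from down to up with the trend removed (adjusted p = 0.049 by limma), and the catalase list after H2O2 turned down by ranks (adjusted p = 0.92 by limma). For both the cause was not tested. Of the named genes 116 of 120 in the mutant and 123 of 124 after H2O2 kept direction and side of the threshold with the trend removed. No paired analysis was possible because the files hold no values per library for the mutant and treated groups. For the same reason a replicate block, leaving out libraries, a joint fit, other normalizations, other tools, pseudocounts, an estimated correlation and fry were not run. The depth of the mutant and treated libraries is unknown. The median standard error was 0.36 over genes with a mean of at least 50. Among such genes the simulated test found 33.6% of those changed by 1 on the log2 scale after H2O2.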

Other observations

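The tests of a constant background and of genes with few reads were chosen only after the result was seen, as were the genes named in the next paragraph outside the rule.

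Called genes lay in runs of consecutive locus tags. Runs of at least 4 tags held 67 of 269 called genes in the mutant and 94 of 299 after H2O2, against at most 4 and 5 in 10000 random placements. The placements treated neighbouring tags as independent. Neighbouring genes that share a transcript are not, so an excess could arise with any set of changed genes. After H2O2 the genes of cytochrome bd oxidase, a terminal oxidase of respiration, fell. Their run SCO3945 to SCO3948 lay between -4.00 and -2.59 in the authors' deposited table. For cydB (SCO3946) the wild-type libraries stood apart, at 11621 and 3248 normalised counts. In the mutant cydA (SCO3945) and cydB were at -0.13 ± 0.68 and 0.35 ± 0.68 without a call in the authors' deposited table, and the difference passed for both (adjusted p of 0.016 and 0.0016, from the authors' DESeq2 errors). Genes of nitrogen regulation, glnK (SCO5584) and glnD (SCO5585), rose after H2O2 by 3.39 ± 0.63 and 3.23 ± 0.60 on the log2 scale in the authors' deposited table. For glnK the wild-type libraries were at 26.3 and 85.0 normalised counts. The run SCO1291 to SCO1294 was higher after H2O2, between 2.01 and 3.82 in the authors' deposited table, and SCO1292 was not called in the mutant, at -0.30 ± 0.33 in the authors' deposited table.

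Log2 fold changes in the mutant fell with abundance, with a slope of -0.124 per doubling of the mean over the 5459 genes with a mean of at least 50 whose wild-type libraries were resolved, few of them above 10000, against -0.0405 after H2O2. Noise that differs between the shared wild-type libraries is argued against, since the slope between them was -0.0204 (95% interval -0.0295 to -0.0121). That was under the limit of 0.0618 in size set before that slope was seen. A shift that both wild-type libraries share would not show in that slope and stays open. A constant background of reads in the mutant libraries is argued against by the excess in genes of middle abundance, 5.25 times (4.77 to 5.80) that in genes of low abundance, and few reads by a slope of -0.0935 (-0.103 to -0.0840) at a mean of at least 100. Other technical differences of the mutant libraries and an effect of genotype or growth stay open, since the design gives 1 strain per group and they fall together. Single genes past the threshold with the trend removed, such as catA and SCO2027, do not rest on it alone.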
